A study of Danio rerio with 6 samples.

How the data were processed

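Expression was measured in 6 samples of total RNA from zebrafish embryos at 48 h after fertilization, 3 injected with a control morpholino and 3 with setb MO1, each on 1 Affymetrix array with biotin-labelled target. The deposited values are log2 intensities of probe sets, and the method named for them is RMA, per the submitters' processing notes. RMA corrects the background, quantile normalises the arrays and summarises the probes of a probe set on the log2 scale. Its version and the software are not given in the sources used here. The values bear this out as far as they can, with array medians of 9.47 to 9.49 and values from 5.11 to 14.1. Every one of the 15726 probe sets reached 8.45 in at least 1 array, so that dim probe sets had been removed after normalization, by a filter that is not given in the sources used here. Detection calls were not used here, and a group mean at a dim level may be background, which would understate a fold change.

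Samples were grouped by the treatment in their labels, and replicate numbers were taken from their titles. Probe sets were named through the platform annotation, whose Entrez identifiers were looked up in a RefSeq gene table (assembly GRCz12tu, used for names only). Of the probe sets, 11738 had 1 gene symbol, 413 had several and 3575 had none. Of those with 1 symbol, 11497 matched the gene table and 241 kept the symbol of the annotation, and the match changed none of the symbols. Genes were named only from probe sets with 1 symbol, and each of the 11304 genes was represented by its probe set with the highest mean over all arrays. For 376 genes with several probe sets, the signs of the changes differed in 71, and 2 genes, crybg2 and rpl37, had probe sets called in both directions.

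The groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values as deposited, two-sided, and Benjamini-Hochberg adjustment over all probe sets or over all genes at a threshold of 0.05. Changes are given as the log2 difference of setb MO1 minus control with its standard error. Fold changes of at least 2 were also counted. On simulated data for the comparison of setb MO1 with control, with 11304 genes of which 200 were changed, the fit recovered 71% of the genes changed 1.5-fold and 94% of those changed 2-fold, and 2.37% of the calls were false. Of 20 simulated lists without a shift, 0 were called. The simulated genes varied independently, and a smaller share was changed than was called in the data. The simulation therefore does not show how often camera calls a list of correlated genes without a shift.

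Gene lists were fixed before the data were examined, 40 in all, from general knowledge of zebrafish tissues, signalling pathways and stress responses. The list of histone genes, with 4 genes measured against a minimum of 5, was not tested, which left 39. Their shifts were tested with camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move on balance one way. Members were counted by their adjusted p over all genes and adjusted over the list alone.

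The rule for named genes was also fixed before the data were examined. It took setb and seta, the 12 genes with the largest change in each direction among those past the threshold whose groups did not overlap, and up to 4 members with the smallest p of each list described, and it passed over clone and locus identifiers. Genes named outside this rule are said to have been chosen after their values were seen.

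Alternatives were a repeated quantile normalization, equal array medians, filters at the 30th percentile and the median of mean level, a trended and robust prior, array weights, the replicate number as a block, other thresholds of 0.01 and 0.1, the mean of the probe sets of a gene, probe sets with several genes kept, other set tests and leaving out each array in turn. Further settings for the lists, without genes on another list and with at least 10 measured genes, were chosen after seeing the data. No scan dates or other batch labels were given in the sources used here, and the number of arrays limits the precision.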

Results

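Gene expression was measured on 6 Affymetrix arrays, each hybridised with total RNA from zebrafish embryos collected 48 h after fertilization. A control morpholino had been injected at the single-cell stage in 3 samples, and a morpholino against setb, named MO1, in the other 3. Morpholinos are modified antisense oligonucleotides that block the translation or the splicing of the transcript they bind. The gene setb and its paralog seta are zebrafish counterparts of SET, a histone chaperone and inhibitor of protein phosphatase 2A. The embryos had been scored as normal-like, mildly or moderately affected, and the labels do not give the class of the embryos in each RNA sample. Expression was given as log2 intensity for 15726 probe sets, with array medians between 9.47 and 9.49. The correlation between arrays across probe sets, which are not independent replicates, was 0.964 to 0.990 in the 6 pairs within a group and 0.884 to 0.930 in the 9 pairs between groups. The number of arrays limits the precision of each value. Nothing in the labels says that replicates came from separate clutches, so that p-values measure the spread between these samples, which may be technical.

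The comparison of the groups asked which transcripts differed in embryos injected with the setb morpholino. The lists of lens, retinal, neuronal and neural progenitor genes shifted lower in setb MO1 embryos, with all 18 lens, 18 of 21 retinal, 41 of 53 neuronal and 31 of 68 progenitor genes fallen. Other progenitor genes rose or did not pass. The largest decrease was that of atoh7, a proneural transcription factor required for retinal ganglion cells, which was 10.2-fold lower, with setb MO1 values at or near the lowest of their arrays, so that the fold may be understated. The lists of p53 targets, with the cell cycle inhibitor cdkn1a at 4.68-fold, and of epidermis genes shifted higher, with 20 of 31 and 19 of 34 genes risen. No list call stood with an estimated correlation, where 3 of 39 lists had an unadjusted p under 0.05. The change was broad, with 5053 of 11304 genes past the threshold (44.7%), of which 2702 rose and 2351 fell. At least 2-fold changes were fewer, with 120 genes higher and 204 lower.

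The transcript of setb itself was not lowered. Its log2 level was 12.51, 12.48 and 12.38 in the control arrays and 12.69, 12.60 and 12.66 in the setb MO1 arrays, a difference of 0.19 ± 0.07 (SE, n = 3 and 3, limma adjusted p = 0.0465). The call on setb was lost when the values were quantile normalised again (adjusted p = 0.0543) and with the replicate number as a block (0.0853). Without a single array it was lost for control replicate 2 (0.107) or 3 (0.117) and for setb MO1 replicate 1 (0.133), 2 (0.0753) or 3 (0.110), and it stood without control replicate 1 (0.0415). The paralog seta was at 11.89, 11.71 and 11.62 in the control arrays and 11.56, 11.54 and 11.50 in the setb MO1 arrays, a difference of −0.21 ± 0.08 that did not pass (adjusted p = 0.0776). It passed after repeated quantile normalization (0.0465), with a trended and robust prior (0.0492), with array weights (0.00949) and without control replicate 3 (−0.27, 0.0369). The weighted fit rested mostly on control replicate 2, with a weight of 58.9 against 0.207 to 0.803 for the others, and the weight estimate did not converge. Whether MO1 blocks translation or splicing is not stated in the labels, and a morpholino that blocks translation need not change the level of its transcript, so these values do not check the labels.

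The 12 genes with the largest decreases were atoh7, vsx1, gjc4a.2, tfap2d, ampd1, nr2e3, shox, sox12, crygm2d1, hes2.2, rorb and tectb. The log2 level of atoh7 was 8.83 ± 0.09 in control and 5.48 ± 0.11 in setb MO1 embryos (SD, n = 3 each), a change of −3.35 ± 0.08 (SE, adjusted p = 7.36e-06). The homeobox gene vsx1, known from retinal bipolar cells, changed by −2.95 ± 0.26, and nr2e3, a nuclear receptor of rod photoreceptors, by −2.48 ± 0.11. The transcription factor genes tfap2d (−2.83 ± 0.16), shox (−2.38 ± 0.14), sox12 (−2.34 ± 0.21), hes2.2 (−2.24 ± 0.14) and rorb (−2.21 ± 0.08) fell by more than 4-fold each. So did the connexin gene gjc4a.2 (−2.86 ± 0.42), the muscle AMP deaminase gene ampd1 (−2.50 ± 0.38), the lens crystallin gene crygm2d1 (−2.33 ± 0.27) and tectb, which encodes a tectorin of the inner ear (−2.18 ± 0.16). Adjusted p-values of the 12 genes were at most 0.00188. The setb MO1 levels of atoh7 and nr2e3, at 5.48 and 5.88, lay near the lowest values of the arrays (5.11 to 5.90), as did gjc4a.2 in setb MO1 replicate 3 (5.32), so that their fold changes may be understated.

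The 12 genes with the largest increases were fosl1a, slc16a9a, cdkn1a, cyp24a1, irf1b, mmp9, prtgb, prtga, duox, cart3, bbc3 and rps27l, with adjusted p-values of at most 0.00319. The AP-1 subunit gene fosl1a, at 8.66 ± 0.58 in control embryos (SD, n = 3), rose by 2.35 ± 0.30 (SE, 5.08-fold). The p53 targets cdkn1a (2.23 ± 0.09), bbc3 (1.68 ± 0.20) and rps27l (1.66 ± 0.12) were among them, bbc3 encoding the pro-apoptotic protein Puma, and fosl1a is on the p53 list as well. Also among them were mmp9, a matrix metalloproteinase (1.79 ± 0.29), irf1b, an interferon regulatory factor (1.85 ± 0.32), and duox, a dual oxidase (1.73 ± 0.17). The protogenin genes prtgb and prtga rose by 1.79 ± 0.22 and 1.77 ± 0.23. The vitamin D hydroxylase gene cyp24a1 rose by 1.99 ± 0.25, the transporter gene slc16a9a by 2.24 ± 0.33 and the neuropeptide gene cart3 by 1.70 ± 0.23.

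**Figure D1:**
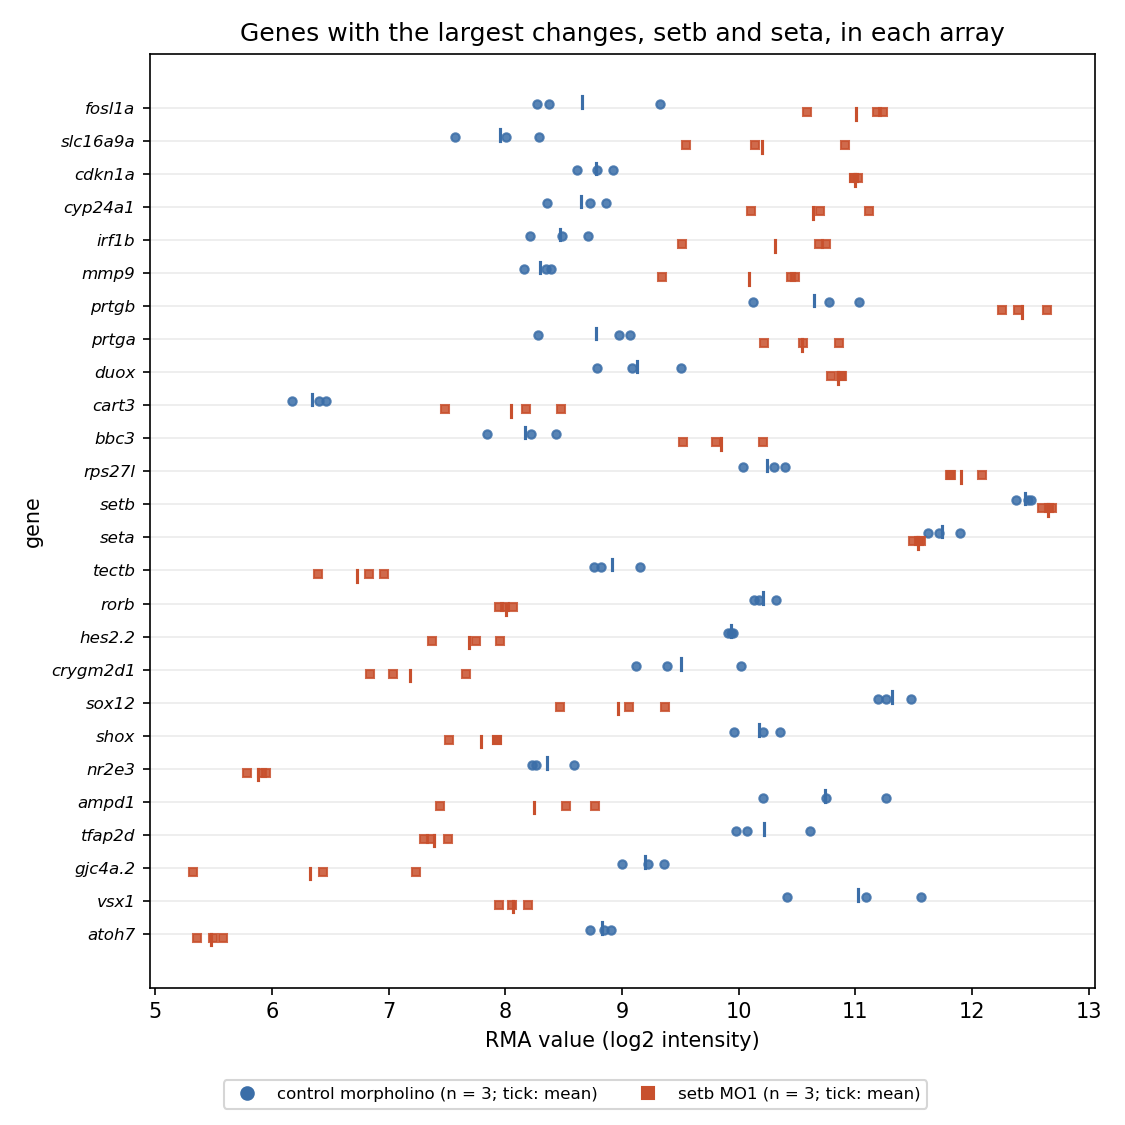
RMA log2 intensity (x axis) of 26 genes (rows) in each of the 3 control morpholino arrays (circles) and the 3 setb MO1 arrays (squares), with ticks at the group means. The 12 genes at the top were higher and the 12 at the bottom lower in all 3 setb MO1 arrays than in any control array, with mean changes from 2.35 for fosl1a to −3.35 for atoh7, while the group means of setb and seta differed by 0.19 and −0.21.

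Lens genes fell as a group. All 18 measured genes of the list of lens crystallins and lens fibre genes fell (18 adjusted over the list alone), with a median log2 change of −1.03 (camera adjusted p = 1.42e-08). The call was lost with an adjusted p = 0.599 with an estimated correlation. The alpha crystallin gene cryaa changed by −1.46 ± 0.15, the lens filament gene bfsp2 by −1.38 ± 0.13, and the gamma crystallin genes crygm2b and crygm2d13 by −1.72 ± 0.17 and −1.79 ± 0.15 (SE, n = 3 and 3). Gamma M crystallin genes are close copies of each other, and their probe sets may share signal. The same 18 of 18 count was found after leaving out any single array. Within the control group, where replicate 2 mostly lay between the others, the median lens gene was also lower in replicate 3 than in replicate 1, by −0.34.

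Of 21 genes of retinal progenitors and inner retinal neurons, 18 fell, 1 rose and 2 did not pass, and the counts adjusted over the list alone were also 18 and 1. The median change was −0.90 (camera adjusted p = 1.42e-08, and adjusted p = 0.188 with an estimated correlation). After atoh7, the smallest p-values on this list belonged to the proneural genes neurod4 (−1.46 ± 0.06) and neurod1 (−1.45 ± 0.10) and to foxn4 (−1.95 ± 0.09), a forkhead factor of amacrine and horizontal cell precursors. The gene that rose was six3b, at 0.44 ± 0.12, named after its value was seen. Of 60 genes on the photoreceptor list 8 were measured, of which 5 fell, 1 rose and 2 did not pass (5 and 1 adjusted over the list alone). Among the 8 were the visual cycle genes rlbp1b, rpe65a and rgra, which need not be genes of photoreceptors. The median was −0.48 (camera adjusted p = 0.0438, and adjusted p = 0.627 with an estimated correlation). The photoreceptor transcription factor genes crx and nrl changed by −2.07 ± 0.22 and −0.36 ± 0.07, and pde6gb, a phosphodiesterase subunit of phototransduction, by −1.65 ± 0.15. The subunit gene pde6hb, also named after its value was seen, rose by 0.74 ± 0.14. The call on the photoreceptor list was lost after repeated quantile normalization (adjusted p = 0.0656), with a trended and robust prior (0.0550), with array weights (0.0641), without control replicate 1 (0.0698) and without setb MO1 replicate 2 (0.0522). From control replicate 1 to 3 the median difference was −0.15 for the retinal and −0.34 for the photoreceptor list.

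Neuronal genes fell as a group. Of 53 genes of differentiated neurons, 41 fell, 1 rose and 11 did not pass (44 and 1 adjusted over the list alone). The median was −0.56 (camera adjusted p = 1.32e-12, and adjusted p = 0.188 with an estimated correlation). The glutamate decarboxylase genes gad2 (−1.58 ± 0.09) and gad1b (−0.87 ± 0.07), which make the transmitter GABA, the synapsin gene syn2a (−0.84 ± 0.06) and the neuronal splicing factor gene rbfox1 (−0.82 ± 0.06) had the smallest p-values. The gene that rose, zic2a (0.41 ± 0.08, named after its value was seen), is also on the list of progenitor genes. Of 68 genes of neural progenitors and brain patterning, 31 fell, 9 rose and 28 did not pass (32 and 11 adjusted over the list alone). The median was −0.24 (camera adjusted p = 0.000157, and adjusted p = 0.599 with an estimated correlation). From control replicate 1 to 3 the median difference was −0.07 for the neuronal and 0.12 for the progenitor list. The homeobox genes lhx1a (−1.82 ± 0.07), otx2b (−1.54 ± 0.09) and dlx1a (−1.05 ± 0.06) fell, as did neurod4, which is on both this and the retinal list. Named after their values were seen, her9 (0.65 ± 0.14) and her3 (0.63 ± 0.12) rose. On the same list sox2 (−0.0017 ± 0.13), sox3 (−0.16 ± 0.13) and nes (−0.17 ± 0.10), also named afterwards, did not pass. The decrease was therefore not shared by all progenitor genes. Of 12 myelin and glial genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.109). Its radial glial genes fabp7a and slc1a3b changed by −1.62 ± 0.13 and −1.0 ± 0.12, while the myelin basic protein gene mbpb rose by 0.37 ± 0.06.

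Of 32 hox genes, 14 fell, 1 rose and 17 did not pass (14 and 1 adjusted over the list alone). The median was −0.15 (camera adjusted p = 0.0249, and adjusted p = 0.627 with an estimated correlation). From control replicate 1 to 3 the median hox gene differed by 0.10, opposite in sign. The genes hoxa13b (−0.68 ± 0.10), hoxa9b (−0.50 ± 0.08), hoxc12b (−0.48 ± 0.08) and hoxb6b (−0.46 ± 0.07) had the smallest p-values, and hoxa1a, named after its value was seen, rose by 0.34 ± 0.08. The hox call was lost without control replicate 3 (adjusted p = 0.0624), without setb MO1 replicate 1 (0.0634) and among probe sets above the median level (0.0884), and the number of hox genes that fell was 6 to 14 when single arrays were left out.

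Targets of p53 and DNA damage genes rose as a group, with 20 of 31 higher, 3 lower and 8 not passed (21 and 3 adjusted over the list alone). The median change was 0.36 (camera adjusted p = 0.00026, and adjusted p = 0.341 with an estimated correlation). After cdkn1a, the smallest p-values belonged to mdm2, the ubiquitin ligase that limits p53 (1.24 ± 0.08), phlda3 (1.22 ± 0.08) and rps27l. The members that fell, named after their values were seen, were the p53 inhibitor gene mdm4 (−0.73 ± 0.16), the cyclin gene ccng2 (−0.61 ± 0.17) and the forkhead gene foxo3a (−0.57 ± 0.07). From control replicate 1 to 3 the median p53 target differed by 0.06. Such genes are known to respond to morpholinos themselves, and the design has 1 morpholino in each group. Of 25 apoptosis genes, 7 rose and 1 fell (4 and 1 adjusted over the list alone), including bbc3, the caspase gene casp8 (1.19 ± 0.20) and baxa (0.44 ± 0.06). The apoptosis list was not called (camera adjusted p = 0.217) and shares 5 genes with the p53 list, bbc3, casp8 and baxa among them. Of 88 DNA replication and cell cycle genes, 12 rose and 20 fell (11 and 16 adjusted over the list alone, camera adjusted p = 0.198). Here cdkn1a rose and the cyclin gene ccne2 fell (−0.73 ± 0.08). The cell cycle list was called among probe sets above the median level (adjusted p = 0.0402).

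Of 34 epidermis and periderm genes, 19 rose, none fell and 15 did not pass (19 and 0 adjusted over the list alone). The median was 0.30 (camera adjusted p = 0.000981, and adjusted p = 0.543 with an estimated correlation). The smallest p-values belonged to the adhesion genes cdh1 (0.57 ± 0.06) and pkp3a (0.64 ± 0.07), the protease inhibitor gene spint1a (0.52 ± 0.07) and icn2 (0.79 ± 0.09). Of these, cdh1, pkp3a and spint1a encode proteins of epithelia at large. Named after their values were seen, tp63 (0.12 ± 0.07), krt4 (0.059 ± 0.056) and krt5 (−0.15 ± 0.09) were among the 15 that did not pass, while krt96 (0.81 ± 0.25) and krt97 (0.40 ± 0.09) rose. From control replicate 1 to 3 the median epidermis gene differed by −0.05. Of 17 hair cell and lateral line genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.122). The otic matrix gene oc90 rose by 1.16 ± 0.10, and epcam (0.53 ± 0.08) and cldna (0.50 ± 0.08), which also rose, are on the epidermis list too. Of 8 hatching gland genes, 5 rose and none fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0569), with examples in the hatching enzyme gene he1.1 (1.03 ± 0.07) and ctslb (0.77 ± 0.07). The hatching gland list was called with a trended and robust prior (adjusted p = 0.0419), without setb MO1 replicate 1 (0.0447) and without genes on another list (0.0127), a setting chosen after seeing the data.

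**Figure D2:**
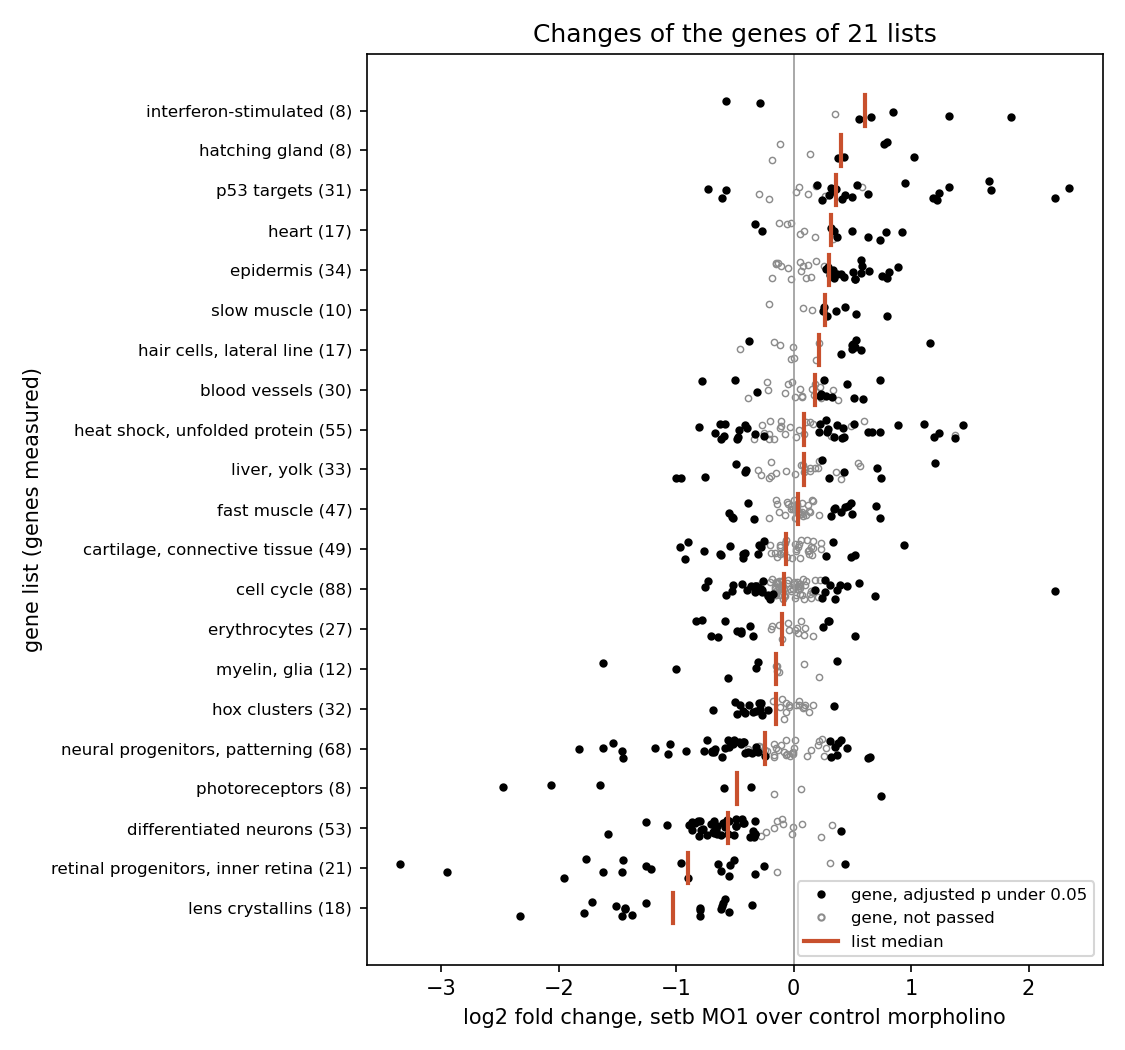
Log2 fold change of setb MO1 over control morpholino embryos (x axis) for each measured gene of 21 lists (rows, with the number of genes measured in brackets), as filled points for genes at a limma adjusted p under 0.05, open points for genes that did not pass and bars for list medians. All 18 lens genes lie to the left of 0 and the list medians run from −1.03 for the lens list to 0.61 for the interferon-stimulated list.

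Heart and muscle lists were not called. The median difference from control replicate 1 to 3 was 0.12 for the heart, 0.19 for the slow muscle and 0.24 for the myogenic regulator list, the same sign as their medians between the groups. Of 17 heart genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0997). The cardiac transcription factor genes gata4 and gata5 rose by 0.92 ± 0.09 and 0.79 ± 0.08, and klf2a (−0.33 ± 0.09) and alcama (−0.27 ± 0.06), named after their values were seen, fell. The heart list was called without genes on another list (adjusted p = 0.0412), a setting chosen after seeing the data. Of 10 slow muscle genes, 7 rose and none fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0569), including prdm1a (0.79 ± 0.09) and the myosin light chain gene myl10 (0.36 ± 0.08). The slow muscle list was called with a trended and robust prior (0.0416), without control replicate 2 (0.0463) and without control replicate 3 (0.0378). Of 47 fast muscle genes, 10 rose and 5 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.454). The myosin chaperone genes unc45b (0.70 ± 0.11) and hsp90aa1.1 (0.73 ± 0.12) rose and the myosin heavy chain gene myhz2 fell (−0.52 ± 0.06). Of 11 myogenic regulators, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.137). The genes that rose were mef2ca (0.47 ± 0.08), myf5 (0.59 ± 0.10) and myf6 (0.47 ± 0.10). The one that fell, pax7a (−0.50 ± 0.14), no longer passed without control replicate 2 (adjusted p = 0.0762) or 3 (0.0569) or setb MO1 replicate 1 (0.0711) or 2 (0.0675).

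Among blood cells and vessels, the 27 erythrocyte genes included 10 that fell and 4 that rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.129). The haem synthesis gene alas2 changed by −0.83 ± 0.06 and the embryonic globin gene hbbe2 by −0.70 ± 0.11. Of 16 myeloid and immune genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.894). The lysozyme gene lyz was at −1.18 ± 0.08 and the transcription factor gene cebpb at 1.19 ± 0.11. Of 30 blood vessel genes, 9 rose and 3 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.198), and 4 to 9 rose without single arrays. The scavenger receptor genes stab1 (0.52 ± 0.08) and stab2 (0.73 ± 0.13) were among those that rose. Of 8 interferon-stimulated genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.108). The inhibitor genes of cytokine signalling socs3a and socs3b rose by 1.32 ± 0.12 and 0.66 ± 0.09, and eif2ak2 (−0.57 ± 0.17) and adar (−0.29 ± 0.08), named after their values were seen, fell. Of 55 heat shock, unfolded protein and oxidative stress genes, 20 rose and 13 fell (20 and 13 adjusted over the list alone, camera adjusted p = 0.787). The AP-1 gene junba was at 1.44 ± 0.16 and the calreticulin gene calr at −0.81 ± 0.09.

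Of 49 genes of cartilage, bone and connective tissue, 5 rose and 14 fell (5 and 14 adjusted over the list alone, camera adjusted p = 0.169). The transcription factor genes sox9b (−0.76 ± 0.06) and dlx4a (−0.97 ± 0.11) fell and the fibronectin gene fn1b rose (0.94 ± 0.08). Of 31 neural crest and pigment cell genes, 5 rose and 8 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.217). The endothelin receptor genes moved in opposite directions, ednrba by −1.03 ± 0.08 and ednrab by 1.03 ± 0.14. Of 33 liver and yolk genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.894). The apolipoprotein gene apoea was at −1.0 ± 0.06 and the ceruloplasmin gene cp at 1.2 ± 0.15. Of 11 pancreas and gut genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.258). Here neurod1 and the carboxypeptidase gene cpa5 (−0.69 ± 0.11) fell and foxa1 rose (0.51 ± 0.08). Of 22 pronephros and ionocyte genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.137). The ion transporter genes slc12a1 and slc12a3 rose by 0.80 ± 0.08 and 0.88 ± 0.10. The pronephros and ionocyte list was called without genes on another list (adjusted p = 0.0412), a setting chosen after seeing the data.

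Signalling pathways held genes of both directions, and no pathway list was called. The median difference from control replicate 1 to 3 was 0.22 for the Notch, 0.22 for the Hedgehog and 0.13 for the forkhead list. Of 27 Notch genes, 6 rose and 11 fell (6 and 12 adjusted over the list alone, camera adjusted p = 0.127), with her13 at −1.14 ± 0.10 and the ligand gene dlc at −0.69 ± 0.07. The Notch list was called without control replicate 1 (0.0466). Of 51 Wnt genes, 16 rose and 10 fell (16 and 10 adjusted over the list alone, camera adjusted p = 0.605). The ligand gene wnt3a was at 1.08 ± 0.13 and the nuclear effector gene tcf7l2 at −0.71 ± 0.06. Of 23 Fgf genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.126). The ligand gene fgf8a was at 1.0 ± 0.08, and the gene that fell was spred3 (−0.77 ± 0.07). Of 45 BMP and TGF-beta genes, 18 rose and 9 fell (19 and 9 adjusted over the list alone, camera adjusted p = 0.361). The follistatin gene fsta was at 1.56 ± 0.09 and the ligand gene gdf11 at −1.24 ± 0.09. Of 19 Hedgehog genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.198). The ligand gene shha (0.53 ± 0.08) and the effector gene gli1 (0.56 ± 0.08) rose. Of 27 retinoic acid genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.947), with aldh1a2 at 0.55 ± 0.06 and rbp2a at −1.32 ± 0.14. Without single arrays, 2 to 6 of them fell. Of 38 forkhead genes, 11 rose and 9 fell (11 and 10 adjusted over the list alone, camera adjusted p = 0.971), with foxb1a at 0.97 ± 0.07 and foxg1b at −1.07 ± 0.08. For the retinoic acid and forkhead lists the median and the mean had opposite signs, −0.037 and 0.011 for the former and 0.038 and −0.010 for the latter.

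Of 44 genes of protein phosphatase 2A, SET-family chaperones and their partners, a list that includes setb and seta, 4 rose and 12 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.152), and 5 to 11 fell without single arrays. The regulatory subunit genes ppp2r2bb (−1.01 ± 0.09), ppp2r5b (−0.74 ± 0.08) and ppp2r2ba (−0.69 ± 0.07) fell and the histone chaperone gene nap1l4a rose (0.53 ± 0.06). Of 32 circadian clock genes, 9 rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.672), with cry2 at 0.54 ± 0.09. Of 65 ribosomal protein genes, none rose and 10 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.0997), and 3 to 9 fell without single arrays. Among the 10, rpl37 (−0.19 ± 0.06) also had a probe set called higher, so that its count here holds for the brightest probe set only. Of 76 oxidative phosphorylation genes, 5 rose and 3 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.609), and 1 to 8 rose without single arrays. Of 42 proteasome genes, 1 rose and 4 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.619). The one that rose was the activator gene psme1 (0.94 ± 0.16), and the median and the mean had opposite signs (0.0022 and −0.011).

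Further members made up counts of 5 or fewer and are named here, most of them chosen after their values were seen. Among eye, ear and glial genes, rlbp1b (−0.60 ± 0.12), otomp (−0.38 ± 0.10) and the myelin and glial genes olig2 (−0.56 ± 0.07), gfap (−0.32 ± 0.08) and csf1ra (−0.30 ± 0.11) fell. In the fast muscle list cacna1sa (−0.55 ± 0.09), pvalb3 (−0.52 ± 0.12), acta1b (−0.39 ± 0.07) and myhz1.1 (−0.34 ± 0.07) fell. The vessel genes tal1 (−0.78 ± 0.13), gata2a (−0.50 ± 0.10) and fli1 (−0.31 ± 0.10) fell, and the erythrocyte genes fech (0.25 ± 0.06), slc25a37 (0.29 ± 0.08), znfl2a (0.30 ± 0.07) and cpox (0.53 ± 0.15) rose. Of the myeloid genes, cebpa (0.33 ± 0.06) and cebpd (0.42 ± 0.09) rose, as did mmp9, and c3a.1 (−0.76 ± 0.12), mpx (−0.52 ± 0.12) and lcp1 (−0.21 ± 0.07) fell, as did csf1ra. The interferon-stimulated genes ifi30a (0.55 ± 0.09) and irf9 (0.85 ± 0.12) and the hatching gland genes cd63 (0.38 ± 0.07) and klf17 (0.43 ± 0.09) rose. In the cartilage list dlx3b (0.27 ± 0.08), col12a1a (0.33 ± 0.08), hapln1b (0.49 ± 0.10) and ogna (0.52 ± 0.11) rose, and in the neural crest list paics (0.23 ± 0.06), snai2 (0.29 ± 0.09), gart (0.45 ± 0.08) and snai1b (0.68 ± 0.16). In the pancreas and gut list foxa3 (0.50 ± 0.09) rose and isl1a (−0.62 ± 0.07), apoa4a (−0.41 ± 0.13) and lgals2a (−0.30 ± 0.10) fell. The pronephros genes slc22a6l (−1.23 ± 0.18) and atp1a1b (−0.40 ± 0.07) fell, as did lhx1a, the Hedgehog genes nkx6.1 (−0.25 ± 0.07) and smo (−0.18 ± 0.06), and birc2 (−0.26 ± 0.07) of the apoptosis list. The clock genes roraa (−0.64 ± 0.12), nfil3-5 (−0.60 ± 0.14), tefb (−0.32 ± 0.10), clockb (−0.29 ± 0.09) and csnk1e (−0.27 ± 0.07) fell. On the phosphatase list lcmt1 (0.41 ± 0.06) and npm1a (0.50 ± 0.08) rose beside setb and nap1l4a. Of the oxidative phosphorylation genes, cox5aa (0.18 ± 0.06), ndufab1a (0.23 ± 0.07), uqcrb (0.27 ± 0.06), ndufs4 (0.31 ± 0.08) and atp5if1a (0.40 ± 0.13) rose and ndufa4b (−0.60 ± 0.07), cox6b1 (−0.49 ± 0.10) and cox5bb (−0.41 ± 0.10) fell, and the proteasome genes that fell were psmf1 (−0.41 ± 0.11), psme4b (−0.33 ± 0.07), psmd1 (−0.20 ± 0.06) and psmd5 (−0.20 ± 0.06). The calls on psmf1, psmd1, adar, apoa4a, atp5if1a, birc2, ccng2, clockb, cpox, csf1ra, csnk1e, dlx3b, eif2ak2, fech, fli1, gfap, lcp1, lgals2a, ndufab1a, ndufs4, nkx6.1, otomp, paics, six3b, slc25a37, snai2, tefb and znfl2a were lost without some single arrays, and those on cox5aa, psmd5 and smo without each one in turn. The calls on csf1ra, lcp1 and lgals2a were also lost after repeated quantile normalization, and that on lcp1 with a trended and robust prior. Of the larger counts, those that changed by more than 1.5-fold without single arrays also included the genes that rose on the progenitor (5 to 11), apoptosis (4 to 7), cell cycle (7 to 16), Notch (3 to 6), Hedgehog (4 to 8) and BMP and TGF-beta lists (11 to 17). The same held for those that fell on the neural crest (5 to 7) and cell cycle lists (12 to 18). Of the counts of 3 to 5, so did the genes that rose on the erythrocyte (0 to 4), neural crest (3 to 5) and myogenic regulator lists (3 to 5). Those that fell did so on the clock (2 to 4), proteasome (1 to 4), vessel (2 to 5), myeloid (3 to 5), glial (3 to 5) and pancreas and gut lists (3 to 5). With the replicate number as a block, psmd1, cox5aa, csf1ra, dlx3b, lcp1, ndufab1a, psmd5 and smo did not pass.

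Of the 39 lists tested, 8 were called by camera, 2 higher and 6 lower, and none was called with an estimated correlation, where 3 had an unadjusted p under 0.05. Camera also called 8 or more lists in 6 of the 9 other splits of the arrays into 3 and 3, up to 14. Those splits have arrays of both groups on each side, so that part of the group difference stays in them. Their counts therefore do not measure chance. At the level of probe sets, 6924 of 15726 passed (44.0%), of which 3563 rose and 3361 fell. The groups did not overlap in 56.5% of probe sets, where chance gives 10% without a filter on level. The filter, met by a probe set high in 1 group only, can raise both shares. Without control replicate 2, the count fell to 4702 probe sets and 3523 genes, and that of probe sets that rose to 2363. The log2 values of this array lay between those of control replicates 1 and 3 in 56.8% of probe sets, against 33.3% if the 3 arrays were alike. Probe sets vary together, so that this share by itself does not measure chance.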

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

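The settings without genes on another list and with at least 10 measured genes were chosen after the results were seen. No result reversed its direction. Of the values of named genes under the alternatives, 3173 kept direction and side of the threshold and 129 fell short of it, and of those of single lists, 653 stayed on their side, 24 passed anew and 16 were lost. Filters test fewer probe sets, and calls became fewer with them. Above the median level there were 3410 probe sets (1849 higher, 1561 lower, 166 at least 2-fold) and 2708 genes (1491 higher, 1217 lower, 133 at least 2-fold). Above the 30th percentile, 2213 probe sets were lower, and 259 probe sets and 191 genes were at least 2-fold changed. At an adjusted p under 0.01 there were 4069 probe sets (2024 higher, 2045 lower) and 3040 genes (1586 higher, 1454 lower). Array weights gave 10602 probe sets (5542 higher, 5060 lower) and 7634 genes (4173 higher), with a weight of 58.9 for control replicate 2 and 0.207 to 0.803 for the others, and the weight estimate did not converge. Leaving out single arrays gave 4702 to 6891 probe sets, of which 2363 to 3541 were higher, and 3523 to 5014 genes, the lowest without control replicate 2. The change of setb was 0.185 after repeated quantile normalization, and 0.155 to 0.221 without single arrays. That of seta was −0.231 after repeated quantile normalization, −0.208 with a trended and robust prior, −0.173 with array weights and −0.269 to −0.132 without single arrays. For the array weights, setb and seta the cause was not tested, and each of the 2 genes had 1 probe set, so that no other could be tried. Camera with an estimated correlation called 0 lists, with 3 at an unadjusted p under 0.05, and fry, which asks another question, called 22. The replicate numbers did not pair the samples, since same-numbered arrays had correlations of their deviations of −0.006, −0.323 and 0.333, so that not every array went best with its own number. With the replicate block, 6622 probe sets, 4789 genes and 8 lists were called, 4566 of the genes shared with the fit without it, and setb was at 0.194 (adjusted p = 0.0853). Signal over background is unknown for dim probe sets, which limits folds against low levels.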

Other observations

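The gene families and all tests of this part were chosen after the results were seen, except the tests of a mixture and of lower oxygen in the control arrays (its comparison with other lists was added afterwards). Among 176 families of at least 8 genes that share the stem of their symbol, camera called 19, 11 higher and 8 lower, and none with an estimated correlation, where 8 had an unadjusted p under 0.05. Of 8 genes named utp, whose products process the small subunit ribosomal RNA, 7 rose and none fell (7 and 0 adjusted over the family alone), with utp25 at 0.81 ± 0.07 and utp4 at 0.76 ± 0.07 (SE, n = 3 and 3). The median was 0.59 (camera adjusted p = 0.00395, and adjusted p = 0.793 with an estimated correlation). Of 24 RNA polymerase subunit genes named polr, 13 rose and 1 fell (14 and 1 adjusted over the family alone, camera adjusted p = 0.00598, and adjusted p = 0.793 with an estimated correlation), and the largest increases were in polr1f (0.83 ± 0.13), polr1b (0.81 ± 0.16) and polr1a (0.78 ± 0.10) of RNA polymerase I.

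Of 14 genes whose symbols begin with wnt, all Wnt ligands, 11 rose and none fell (12 and 0 adjusted over the family alone, camera adjusted p = 0.00363, and adjusted p = 0.793 with an estimated correlation), among them wnt3a, wnt1 (0.86 ± 0.13) and wnt4 (0.75 ± 0.09). Of 24 protocadherin genes, whose products mediate adhesion between neurons, 19 fell and none rose (19 and 0 adjusted over the family alone, camera adjusted p = 1.75e-05, and adjusted p = 0.793 with an estimated correlation), with a median of −0.65. The clustered genes pcdh2ab10 (−1.42 ± 0.16) and pcdhb (−1.32 ± 0.09) are members of clusters of similar copies, for which shared signal between probe sets was not excluded, while pcdh9 (−1.17 ± 0.14), pcdh11 (−0.86 ± 0.08) and pcdh17 (−0.68 ± 0.07) lie outside these clusters.

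Lens, retinal and neuronal genes were lower in setb MO1 embryos, and a lower share of eye and neural cells with no other change may be set against it. That explanation needs the markers of other tissues to shift alike, and the shift of the epidermis list exceeded that of the cartilage and connective tissue list by 0.40 (95% interval over arrays 0.32 to 0.47). This cannot decide the question, since both lists were picked after their shifts were seen. The cartilage list also holds dlx2a (−0.43 ± 0.07) of the progenitor list, so that fewer neural cells could lower it too. Among all genes, 120 rose at least 2-fold and 204 fell at least 2-fold, while the epidermis list shifted by a mean of 0.30. Increases this unequal argue, for those 120 genes, against a lower share with no other change. A lower share together with other changes stays open. For a delay of development in every tissue, 115 late genes of other tissues shifted by a mean of −0.065 (95% interval −0.13 to 0.0045), with 17 risen and 31 fallen. The interval lay above the bound of −0.25, so that a mean shift of that size was not seen in these genes. A smaller delay cannot be told apart from none, since the interval includes 0. In 10 splits of the arrays the real one, 1 of 10, gave the most limma calls, 6924 probe sets (highest other 0, and 691 at an unadjusted p under 0.05) and 5053 genes (highest other 0, and 427), while 7 of 10 gave at least 8 lists (highest other 14), and the splits are too few for a share under 0.05. The other splits have arrays of both groups on each side. Part of the group difference stays in them and widens the spread within a side, so that their counts do not measure chance. Whether the lower eye and brain genes came through the block of setb or another action of its morpholino stays open, since each group had 1 morpholino. A second morpholino against setb would be needed, and the design has none.

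Targets of p53 were higher in setb MO1 embryos, with a median of 0.36. An unspecific p53 response, as morpholinos can give, cannot be told apart from a response to the block of setb, since the design has 1 morpholino in each group and no group without p53. The same holds for the increases of cdkn1a, bbc3, mdm2 and casp8.

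Control replicate 2 lay between control replicates 1 and 3 in 56.8% of probe sets (33.3% if the arrays were alike), and a candidate explanation is that its RNA is a mixture of theirs. On the linear scale the share of replicate 1 in it was 41.2% from 87 probe sets higher in replicate 3 and 42.2% from 37 lower ones, a difference of −0.952 percentage points (95% bootstrap interval −6.76 to 5.08), as a mixture would give. The interval is over probe sets, which vary together, and not over arrays. A separate sample that lies between the others is therefore not excluded. Genes of the response to low oxygen that stood out between the control arrays included the prolyl hydroxylase gene egln3, at 6.95, 9.90 and 10.44 in control replicates 1, 2 and 3 and 10.16, 10.29 and 10.96 in the setb MO1 arrays. Across the 9 such genes seen first, the mean was 8.68 in control replicate 1 and 10.2 to 10.8 in the other arrays. Of 67 further targets of that response, fixed from general knowledge, 49 were higher in replicate 3 than in replicate 1. Their median difference of 0.24 lay above that of each of 10000 random lists. But lists of myogenic (0.24), Notch (0.22) and lens genes (−0.34) differed about as much or more between the same 2 arrays. Lower oxygen in replicate 3 can therefore not be told apart from other differences between single arrays. The mean of the 67 targets was 9.93, 10.05 and 10.20 in control replicates 1, 2 and 3 and 10.12 to 10.27 in the setb MO1 arrays. Replicate 1 was the lowest, but replicate 2 was nearer to it than to replicate 3, unlike in the 9 genes seen first. A mixture would leave 2 independent control samples and p-values that are too small, the count without this array was 3523 genes, and the labels name no biological difference between the control arrays.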
